A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

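The 12 two-colour arrays measured transcript levels in 3 yeast strains without and with rapamycin, with 2 cultures from independent colonies in each of the 6 groups, per the labels. Strain, treatment and dye orientation were taken from the labels and the design text. The suffix r in the labels was read as rapamycin because the design text describes the treated and untreated groups. Replicates are the 2 cultures, never spots or genes.

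The arrays were scanned with an Agilent G2565BA scanner and the spots were read with Imagene, per the labels' protocols. The version of Imagene and any test the authors ran are not given in the sources used here. The deposited scanner files hold the intensity of each spot and its background in both channels, not normalized, per the file headers. The authors also deposited normalized intensities for both channels, made by LOESS within each print tip with a span of 0.4 on the gene probes and no background subtraction, per the labels' protocols. Spots scored as absent or nearly saturated did not enter their curve, and a correction for gene-specific dye bias followed, per the same protocols. External control RNA was added to the amplification mix, per the protocols. The deposited value table holds log2(sample/reference) of these normalized intensities with both dye orientations turned the same way, checked against the intensities (largest difference 4.99e-06), with array medians from -0.00904 to 0.0105. A value above 0 means more transcript in the culture than in the common reference, which cancels in every comparison.

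The main values were computed here from the scanner intensities (signal mean and background median). Each array has 15552 spots: 12776 gene spots for 6388 gene probes, each spotted 2 times, 1872 external control spots and 904 blank or quality control spots. In R 4.3.3 with limma 3.58.1, background was corrected by normexp with an offset of 50, and log2 ratios were normalized within each array by global loess on gene spots (span 0.3, 4 iterations). Ratios were turned to culture over reference by the dye, and the 2 spots of a probe were averaged. No probe was left out for low signal in the main analysis. A probe counts as above the blanks where its signal exceeds percentile 95 of the blank spots, and as saturated above 32768. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.

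Signal over background was 8.25 to 21.6 on 11 arrays and 1.61 on the array of treated wild-type culture a, whose median signal was 69.7 against 412 to 1231. On that array 71.3% of the probes were above the blanks, against 95.6% to 99.5% on the others. The SD of duplicate spots on the log2 scale was 0.0300 to 0.0385. The ratios computed here had a correlation across genes with the value table of 0.479 on the dim array and 0.647 to 0.946 on the others.

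Groups were compared with limma (1 mean per group, all 12 arrays in the fit, moderated t tests, two-sided), with 6 residual and 3.00 prior degrees of freedom. The 8 comparisons were rapamycin against none within each strain, the difference of these effects between each pair of strains, and each untreated tagged strain against untreated wild type. Benjamini-Hochberg adjustment ran over the 6388 probes of each comparison, with a threshold of 0.05. The SE pools the spread of all groups and is moderated by the prior, so that the spread of a group left with 1 array in the runs without that array is taken from the others.

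The letters a and b stand for the dye orientation in every group. The deviations of arrays with the same letter from their group means had correlations across genes of 0.483 to 0.817 over the 15 pairs of groups (median 0.66), all above 0.1, so that the letters pair the arrays, through the dye at least. The main fit has no block, as fixed beforehand, and the fit with the letter as a block, which is an additive dye term, has 5 residual and 4.11 prior degrees of freedom. The median over genes of the absolute mean difference between the letters was 0.0981. The spread within groups after this difference was 0.046 to 0.066, scaled as an SD, so these figures are not on the same scale.

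Gene names came with the arrays: 5326 probes have 1 gene symbol, 1062 have none and 0 have several. Of the symbols, 5266 matched the reference gene table by symbol or locus tag, 58 by synonym and 2 not at all. These make 5311 distinct genes, and 15 probes share a gene with another probe. Probes without a symbol were tested and counted with the rest but are not named.

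The genes named always include MOT1, NCB2, BUR6 and SPT15. Within a strain, the 10 highest and 10 lowest genes by log2 change were named among those past the threshold with the same sign in both letters, and in the other comparisons the 5 highest and 5 lowest. Where none passed, the 5 with the smallest p are given as values. In each list with a changed member or a passed test, up to 4 members with the largest absolute change could be named. Genes named outside this rule were chosen after their values were seen: BNA4, HSP30, HO in Mot1-FRB, HEM13 within each strain, MED6 under rapamycin, and the genes of the groups in the closing section.

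The 29 gene lists were fixed before the values were tested: ribosomal protein, ribosome biogenesis, nitrogen catabolite repression (Gln3/Gat1), retrograde (Rtg1/Rtg3), environmental stress (Msn2/Msn4), heat shock factor (Hsf1) chaperone, amino acid biosynthesis (Gcn4), methionine and sulfate assimilation, galactose, phosphate (Pho4), hexose transporter, glucose-repressed carbon metabolism, glycolysis, respiratory chain, meiosis and sporulation, pheromone response and mating, MATa-specific, MATα-specific, seripauperin and TIR, subtelomeric helicase and COS, iron regulon (Aft1), histone, pleiotropic drug resistance, SAGA subunit, general transcription initiation, cell wall integrity, G1/S and mitotic cyclin, ergosterol and phospholipid (UASINO) genes. They were written from general knowledge of yeast, and the name pattern for ribosomal proteins also takes in RPP1, a subunit of RNase P. Lists were tested with camera (inter-gene correlation 0.01, two-sided), which asks whether list members rank differently from all other genes, with Benjamini-Hochberg adjustment over the 29 lists. Camera was run again with the correlation estimated from the residuals of each list. Fry, which asks whether list members differ from 0 and uses the residual variation of the arrays, was a further alternative. Counts adjusted over the list alone use Benjamini-Hochberg over its members only.

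The alternatives tried were the letter block, no background correction, print-tip loess, median centring, centring on external control spots, the authors' values, leaving out the 25% dimmest probes, fitting only the groups compared, a change of at least 1.5-fold, each array left out in turn, and for lists the estimated correlation and fry. External control centring used the 4 of 14 control probes brighter than the median gene spot, a limit set after the values were seen. Combining the block with the authors' values, or with the dim wild-type array left out, was added after the data had been seen. Tests of promoter TATA elements and of distance to chromosome ends were not run, and no slide or scan information was used.

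The analysis was tested on simulated data made from the spread of these arrays, with 200 of 6388 probes changed by known amounts. In the comparison within Mot1-FRB the main fit recovered 82.1% of 1.5-fold, 97.0% of 2-fold and 100% of 3-fold changes and called 0 of 6163 unchanged probes. In the comparison within wild type it recovered 73.1%, 91.0% and 100% and called 1 of 6163. All simulated arrays had the same noise per gene, so the poorer signal of the dim wild-type array was not part of the simulation. With the block, 97.0%, 100% and 100% were recovered in the former and 95.5%, 100% and 100% in the latter, with 11 and 14 unchanged probes called. A simulated set of 25 genes shifted by 0.3 was recovered by camera, and 0 of the 29 lists were called. The simulated noise was drawn independently for each gene, so this does not test camera on lists whose members vary together.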

Results

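Transcript levels of budding yeast (Saccharomyces cerevisiae) were measured on 12 two-colour microarrays. The arrays covered 3 strains, each grown without and with rapamycin, with 2 cultures from independent colonies (a and b) in each of the 6 groups. The strains were a wild type (HHY168), a strain with FRB-tagged Mot1 (YGP200) and a strain with FRB-tagged NC2β, the product of NCB2 (YGP201). FRB is the rapamycin-binding domain of the Tor kinase. In the anchor-away system, rapamycin ties an FRB-tagged protein to a ribosomal protein fused to FKBP12, and the tagged protein leaves the nucleus with the ribosomal subunits. Mot1 is an ATPase that takes the TATA-binding protein (TBP, encoded by SPT15) off DNA. NC2, made of NC2α (BUR6) and NC2β (NCB2), binds TBP on DNA and keeps other initiation factors out. The series title names how closely Mot1 and NC2β cooperate in transcription, and their relation to the SAGA coactivator, as its subject. Rapamycin was present at 1 µg/ml for 60 min, in groups read from the sample labels.

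Each array set the cRNA of 1 culture against a common reference of untreated wild-type cRNA, with the culture in Cy3 for letter a and in Cy5 for letter b. All values below are log2 differences ± SE from limma with 2 arrays per group, and adjusted p-values are Benjamini-Hochberg values over 6388 gene probes. A gene is said to have risen or fallen where its adjusted p was under 0.05. The SE pools the spread of all 6 groups, with a median of 0.0903 for a rapamycin effect within a strain, and the number of arrays limits the precision. The block mentioned beside some results adds the letter, which is also the dye orientation, to the fit.

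MOT1 rose 2.12-fold in Mot1-FRB cells with rapamycin (1.09 ± 0.095, adjusted p = 5.6e-05) and also rose in NCB2-FRB cells, where it carries no tag (1.07 ± 0.095, adjusted p = 4.2e-05). NCB2 also rose in both, by 0.78 ± 0.18, adjusted p = 0.0078 in Mot1-FRB cells and 0.64 ± 0.18, adjusted p = 0.0181 in NCB2-FRB cells. SPT15 rose in NCB2-FRB cells (0.48 ± 0.071, adjusted p = 0.00076) and had 0.20 ± 0.071, adjusted p = 0.0551 in Mot1-FRB cells, where the adjusted p was 0.0107 with the block, 0.0196 with print-tip loess, 0.0133 with the authors' values and 0.0362 without treated NCB2-FRB culture a or b. BUR6 rose slightly in both, by 0.15 ± 0.052, adjusted p = 0.0467 and 0.18 ± 0.052, adjusted p = 0.0232, although centring on external control spots turned its Mot1-FRB value to -0.0096. In wild-type cells with rapamycin the values were 0.00075 ± 0.095 for MOT1, -0.015 ± 0.18 for NCB2, -0.034 ± 0.052 for BUR6 and 0.095 ± 0.071 for SPT15, all with an adjusted p of 1.

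Per group, the mean log2(sample/reference) of MOT1 was 0.065 ± 0.12 in untreated and 0.066 ± 0.041 in treated wild type (SD, n = 2). It was 0.74 ± 0.061 and 1.83 ± 0.072 in Mot1-FRB, and 0.15 ± 0.11 and 1.22 ± 0.15 in NCB2-FRB cells. NCB2 had -0.022 ± 0.20 and -0.037 ± 0.17 in wild type, 0.41 ± 0.19 and 1.19 ± 0.24 in Mot1-FRB, and -0.67 ± 0.19 and -0.035 ± 0.24 in NCB2-FRB cells. In the same order, BUR6 had 0.026 ± 0.020, -0.0077 ± 0.00047, 0.070 ± 0.029, 0.22 ± 0.0018, 0.020 ± 0.044 and 0.20 ± 0.0061, and it was below the blank spots on 1 array of each wild-type group. SPT15 had -0.12 ± 0.020, -0.024 ± 0.095, 0.13 ± 0.013, 0.32 ± 0.020, 0.060 ± 0.042 and 0.54 ± 0.11.

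The MOT1 rise exceeded that of wild type in both strains, by 1.09 ± 0.13, adjusted p = 0.00116 and 1.07 ± 0.13, adjusted p = 0.000833. For NCB2 the excess over wild type was 0.79 ± 0.25, adjusted p = 0.0558 in Mot1-FRB (block, adjusted p = 2.49e-05) and 0.65 ± 0.25, adjusted p = 0.0945 in NCB2-FRB cells (block, adjusted p = 4.28e-05). With print-tip loess or the authors' values NCB2 passed in both strains, and in Mot1-FRB it also passed on leaving out the dim probes (0.0487), treated Mot1-FRB culture b (0.0472) or treated NCB2-FRB culture a or b (0.0451). For BUR6 the excess was 0.19 ± 0.073, adjusted p = 0.116 and 0.21 ± 0.073, adjusted p = 0.0692 (block, adjusted p = 0.0257 and 0.0134, and 0.0064 and 0.00372 with the authors' values). The NCB2 calls ended without untreated culture b or treated culture a of the strain concerned. Over the runs with 1 array left out, the NCB2 change was 0.60 to 0.95 in Mot1-FRB and 0.47 to 0.81 in NCB2-FRB cells. Leaving out an array leaves 1 dye orientation in its group, and these runs had no dye term. A lost call may therefore come from the dye as well as from the culture. The BUR6 call in Mot1-FRB ended whichever of the 12 arrays was left out (adjusted p up to 0.199), and in NCB2-FRB it ended without untreated culture b or either treated culture (up to 0.133). Transcript levels do not show how much tagged protein stayed in the nucleus.

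**Figure D1:**
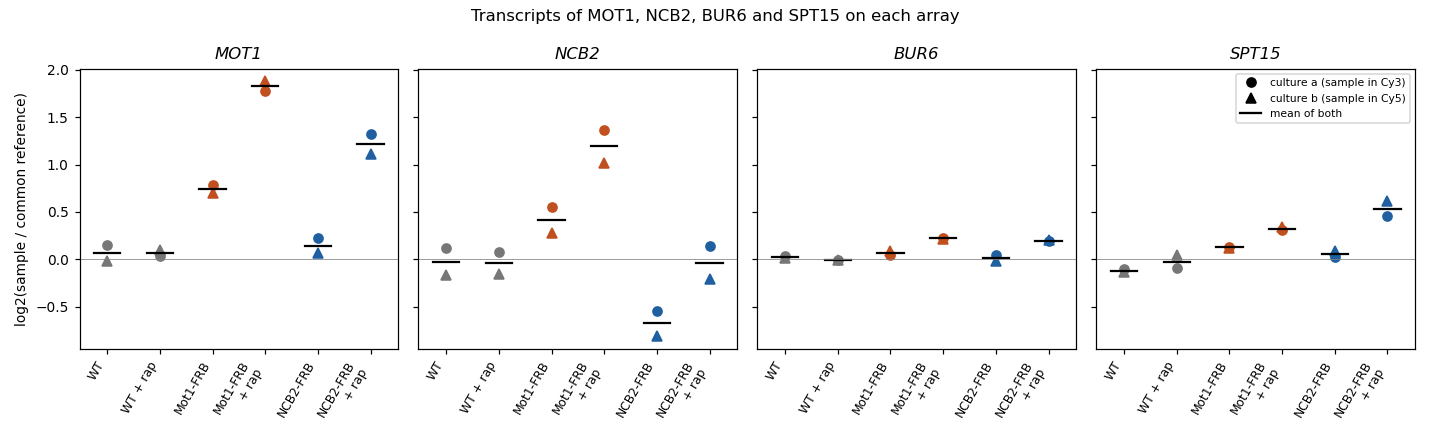
Log2(sample/reference) of MOT1, NCB2, BUR6 and SPT15 on the y axis in the 6 groups on the x axis, with 1 point per array (letters a and b) and a line at each group mean of 2 arrays. MOT1 rose by 1.09 in Mot1-FRB and 1.07 in NCB2-FRB cells and had a change of 0.00075 ± 0.095 in wild type, while BUR6, which rose by 0.15 and 0.18 in the tagged strains, turned to -0.0096 in Mot1-FRB cells with centring on external controls.

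In Mot1-FRB cells, rapamycin raised 1403 genes and lowered 978 of 6388. The largest rises included RTC3 (2.57 ± 0.23, adjusted p = 5.9e-05), MSC1 (2.36 ± 0.20), the glutamate decarboxylase gene GAD1 (2.36 ± 0.13), the small chaperone gene HSP26 (2.35 ± 0.27) and HSP12, which encodes a membrane-stabilising stress protein (2.29 ± 0.29). INO1, the inositol-3-phosphate synthase gene, rose by 2.18 ± 0.23, adjusted p = 0.000125. The ornithine aminotransferase gene CAR2 rose by 2.16 ± 0.14, the inducible Hsp70 gene SSA4 by 2.17 ± 0.14, BDH2 by 2.23 ± 0.21 and WSC4 by 2.11 ± 0.12. Among the genes that fell, MF(ALPHA)2, an α-factor pheromone gene, had -1.33 ± 0.14, adjusted p = 0.000154. The ribosome assembly genes UTP14 (-1.08 ± 0.093) and NOP56 (-0.99 ± 0.14) fell, as did TRM112, which encodes a partner of methyltransferases (-0.99 ± 0.086), YMR321C (-1.07 ± 0.075), the anaphase-promoting complex gene SWM1 (-0.98 ± 0.096) and the translocon gene SSS1 (-0.95 ± 0.083).

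Of the genes called in Mot1-FRB, 734 changed at least 1.5-fold, 596 up and 138 down, and 213 rose and 6 fell at least 2-fold. The block called 3982 genes, 2165 up and 1817 down. Median centring in place of loess called 507 genes, 376 up and 131 down, and centring on external control spots called 788 up and 1719 down, with the median of all genes shifted by -0.16. The seryl-tRNA synthetase gene SES1 (-1.18 ± 0.27, adjusted p = 0.00854), the methionine salvage gene SAM4 (-1.02 ± 0.23, adjusted p = 0.00742) and the zinc-regulated gene ZPS1 (-1.20 ± 0.33, adjusted p = 0.0188) fell too. The calls of SES1 and SAM4 were lost without untreated culture a or treated culture b of Mot1-FRB, and that of ZPS1 without untreated culture b or treated culture a. Over the runs with 1 array left out, the changes were -1.42 to -0.95 for SES1, -1.21 to -0.83 for SAM4 and -1.66 to -0.75 for ZPS1. As above, the losses may come from the dye as well as from the culture.

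Stress, chaperone and cell wall lists passed camera upward in Mot1-FRB cells with rapamycin. Of 48 measured environmental stress (Msn2/Msn4) genes, 43 rose and 0 fell (45 and 0 adjusted over the list alone). Its median was 1.40 (camera adjusted p = 1.73e-17, adjusted p = 0.21 with an estimated correlation). Of 26 heat shock factor (Hsf1) chaperone genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone, 20 and 1 with the block). Its median was 0.43 (camera adjusted p = 1.5e-05, adjusted p = 0.206 with an estimated correlation). HSP42 (1.97 ± 0.20) and the disaggregase gene HSP104 (1.65 ± 0.22) were examples. Of 18 cell wall integrity genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, 13 and 0 with the block). Its median was 0.45 (camera adjusted p = 0.00588, adjusted p = 0.404 with an estimated correlation), and the authors' values gave a camera adjusted p of 0.0778. PST1 rose by 1.20 ± 0.12 and the cell wall MAP kinase gene SLT2 by 0.89 ± 0.13. Of 22 seripauperin and TIR wall genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 20 and 0 with the block). Its median was 0.38 (camera adjusted p = 0.00271, adjusted p = 0.503 with an estimated correlation), and TIR3 rose by 1.30 ± 0.080. Members of the PAU family are near-identical and may share signal by cross-hybridisation.

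Lists of nitrogen, sulfur, lipid and carbon genes had these results in Mot1-FRB cells. Of 25 nitrogen catabolite repression (Gln3/Gat1) genes, 17 rose and 0 fell (20 and 0 adjusted over the list alone). Its median was 0.45 (camera adjusted p = 1.5e-05, adjusted p = 0.206 with an estimated correlation). Among them were UGA1, for GABA use (1.53 ± 0.11), and the allantoin genes DAL3 (1.23 ± 0.17) and DAL5 (0.95 ± 0.13). Of 8 retrograde (Rtg1/Rtg3) genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Its median was 0.70 (camera adjusted p = 0.00201, adjusted p = 0.21 with an estimated correlation), and the isocitrate dehydrogenase gene IDH1 rose by 1.12 ± 0.14. Of 24 methionine and sulfate assimilation genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone, 17 and 1 with the block). Its median was 0.39 (camera adjusted p = 0.000118, adjusted p = 0.206 with an estimated correlation). The ATP sulfurylase gene MET3 rose by 1.64 ± 0.083 and the APS kinase gene MET14 by 1.21 ± 0.090. Of 23 ergosterol genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone, 20 and 1 with the block). Its median was 0.39 (camera adjusted p = 0.000354, adjusted p = 0.206 with an estimated correlation), and ERG28 rose by 0.83 ± 0.14. Of 15 phospholipid (UASINO) genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Its median was 0.32 (camera adjusted p = 0.0029, adjusted p = 0.21 with an estimated correlation). These included INO1 and the phosphatidylserine decarboxylase gene PSD1 (0.99 ± 0.10). Of 16 phosphate (Pho4) genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone). Its median was 0.18 (camera adjusted p = 0.0407, adjusted p = 0.206 with an estimated correlation), and PHM8 rose by 1.93 ± 0.081. Of 17 glycolysis genes, 8 rose and 0 fell (12 and 0 adjusted over the list alone, 16 and 0 with the block). Its median was 0.40 (camera adjusted p = 0.0017, adjusted p = 0.21 with an estimated correlation), and with the authors' values the camera adjusted p was 0.606. PGK1, for phosphoglycerate kinase, rose by 0.81 ± 0.17. TDH1 was saturated on both arrays of both Mot1-FRB groups, so its change is not given.

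Lists of growth and transcription genes had these results in Mot1-FRB cells. Of 126 ribosomal protein genes, 0 rose and 58 fell (0 and 61 adjusted over the list alone, 0 and 96 with the block). Its median was -0.30 (camera adjusted p = 2.2e-13, adjusted p = 0.0073 with an estimated correlation). RPL36A (-0.65 ± 0.082) and RPL37B (-0.63 ± 0.081) were examples. Of 49 ribosome biogenesis genes, 0 rose and 35 fell (0 and 41 adjusted over the list alone). Its median was -0.40 (camera adjusted p = 4.84e-13, adjusted p = 0.206 with an estimated correlation), and PWP2 (-0.72 ± 0.095) and UTP15 (-0.71 ± 0.073) were examples. Of 21 G1/S and mitotic cyclin genes, 10 rose and 0 fell (11 and 0 adjusted over the list alone, 16 and 1 with the block). Its median was 0.29 (camera adjusted p = 0.0017, adjusted p = 0.21 with an estimated correlation), and the G1 cyclin gene PCL1 rose by 0.86 ± 0.13. Of 10 histone genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 9 and 0 with the block). Its median was 0.36 (camera adjusted p = 0.0155, adjusted p = 0.21 with an estimated correlation), and median centring gave 0.0794. HTA2, for histone H2A, rose by 0.53 ± 0.066 and was saturated on 1 array of each Mot1-FRB group. Of 18 SAGA subunit genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, 2 and 11 with the block). Its median was -0.16 (camera adjusted p = 0.0211, adjusted p = 0.21 with an estimated correlation), and print-tip loess gave 0.0512 and median centring 0.0952. HFI1 (-0.58 ± 0.12) and the acetyltransferase gene GCN5 (-0.46 ± 0.083) fell, and SGF11 rose by 0.56 ± 0.066.

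The other lists did not pass camera in Mot1-FRB cells. Of 37 general initiation genes, 6 rose and 9 fell (7 and 9 adjusted over the list alone, 7 and 19 with the block) (camera adjusted p = 0.0585, with the block 0.0336, with median centring 0.0492, and 0.206 with an estimated correlation), and the 6 that rose included MOT1 and NCB2. Of 18 pleiotropic drug resistance genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, 11 and 2 with the block) (camera adjusted p = 0.0585, and 0.0489 with print-tip loess or 0.0371 with external control centring), and the efflux pump gene PDR5 rose by 1.21 ± 0.17. Of 41 amino acid (Gcn4) genes, 13 rose and 4 fell (13 and 5 adjusted over the list alone, 17 and 9 with the block) (camera adjusted p = 0.344), and LYS9 rose by 1.04 ± 0.063. Of 29 glucose-repressed genes, 10 rose and 3 fell (12 and 3 adjusted over the list alone, 14 and 7 with the block) (0.266), and of 36 respiratory chain genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, 14 and 6 with the block) (0.197), with SDH2 at 0.88 ± 0.062. Of 63 meiosis genes, 11 rose and 3 fell (9 and 2 adjusted over the list alone, 21 and 9 with the block) (0.48), and of 25 pheromone response genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, 12 and 4 with the block) (0.266). Of 16 hexose transporter genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone, 5 and 5 with the block) (0.355), and of 10 galactose genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 3 and 3 with the block) (0.671). Of 24 iron regulon (Aft1) genes, 2 rose and 2 fell (0 and 2 adjusted over the list alone, 8 and 5 with the block) (0.653), and of 12 subtelomeric helicase and COS genes, whose copies are near-identical, 2 rose and 0 fell (1 and 0 adjusted over the list alone, 8 and 2 with the block) (0.266). Of 7 MATa-specific genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 1 with the block) (0.63), and of 4 MATα-specific genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, 2 and 1 with the block) (0.671), these being STE3 (0.25 ± 0.064) and MF(ALPHA)2. STE3 lost its call without untreated culture a (adjusted p = 0.109) or treated culture b (0.101) of Mot1-FRB.

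In Mot1-FRB cells 2 lists had values of opposite sign: the galactose list had a median of -0.021 and a mean of 0.15, and the MATα list a median of 0.044 and a mean of -0.23, and camera pointed down in both. List medians near 0 took the other sign under another scaling. Centring on external controls gave -0.14 for Gcn4 genes, -0.11 for glucose-repressed, -0.10 for respiratory, -0.12 for meiosis, -0.053 for pheromone response and -0.12 for MATα genes. Median centring gave 0.18 for galactose, 0.058 for hexose transporter and 0.096 for MATa genes. Print-tip loess turned the galactose, MATa and MATα medians, and the authors' values turned the galactose and MATa medians.

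In NCB2-FRB cells, rapamycin raised 1454 genes and lowered 1163 of 6388. PHM8, a phosphatase gene of the phosphate response, rose by 2.46 ± 0.081, adjusted p = 1.44e-06, CAR2 by 2.39 ± 0.14, HSP26 by 2.38 ± 0.27, RTC3 by 2.38 ± 0.23 and MSC1 by 2.32 ± 0.20. MTD1, a folate dehydrogenase gene, rose by 2.23 ± 0.14, the chaperone gene HSP42 by 2.17 ± 0.20, WSC4 by 2.26 ± 0.12, BDH2 by 2.04 ± 0.21 and the stress gene DDR2 by 2.02 ± 0.18. MF(ALPHA)2 fell 6.61-fold (-2.72 ± 0.14, adjusted p = 6.03e-06), the largest fall in this strain. HO, the endonuclease gene of mating-type switching (-1.83 ± 0.11, adjusted p = 8.31e-06), SES1 (-1.46 ± 0.27, adjusted p = 0.00262) and the α-agglutinin gene SAG1 (-1.31 ± 0.13, adjusted p = 8.4e-05) fell. The cell wall gene TIP1 (-1.27 ± 0.21), the aminopeptidase gene AAP1 (-1.14 ± 0.11), GDS1 (-1.09 ± 0.096), YDL085C-A (-1.03 ± 0.10), YMR321C (-1.0 ± 0.075) and the tRNA acetylation gene TAN1 (-1.0 ± 0.16) also fell.

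Of the genes called in NCB2-FRB, 848 changed at least 1.5-fold, 693 up and 155 down, and 250 rose and 10 fell at least 2-fold. The block called 4001 genes, 2032 up and 1969 down, and median centring called 484 up and 212 down.

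Stress, chaperone, nitrogen catabolite repression and ergosterol genes were among the lists that passed camera upward in NCB2-FRB cells with rapamycin. Of the 48 environmental stress genes, 42 rose and 0 fell (43 and 0 adjusted over the list alone). Its median was 1.21 (camera adjusted p = 6.16e-15, adjusted p = 0.246 with an estimated correlation), and HSP12 rose by 2.01 ± 0.29. Of the 26 Hsf1 chaperone genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone). Its median was 0.61 (camera adjusted p = 8.94e-07, adjusted p = 0.193 with an estimated correlation). PIC2 (1.42 ± 0.14) and the mitochondrial chaperone gene HSP78 (1.35 ± 0.17) were examples. Of the 25 nitrogen catabolite repression genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone). Its median was 0.55 (camera adjusted p = 3.34e-07, adjusted p = 0.103 with an estimated correlation), and the proline oxidase gene PUT1 rose by 1.70 ± 0.15 and the GATA repressor gene DAL80 by 1.65 ± 0.21. Of the 23 ergosterol genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone). Its median was 0.66 (camera adjusted p = 1.6e-08, adjusted p = 0.103 with an estimated correlation). ERG28 rose by 1.32 ± 0.14 and the mevalonate kinase gene ERG12 by 1.09 ± 0.090. Of the 22 seripauperin and TIR genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone, 21 and 1 with the block). Its median was 0.44 (camera adjusted p = 0.000405, adjusted p = 0.38 with an estimated correlation). Of the 18 drug resistance genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). Its median was 0.53 (camera adjusted p = 0.000902, adjusted p = 0.323 with an estimated correlation), and the transporter genes TPO4 (1.29 ± 0.13) and SNQ2 (1.07 ± 0.092) rose. Of the 18 cell wall integrity genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone). Its median was 0.37 (camera adjusted p = 0.00228, adjusted p = 0.299 with an estimated correlation), and SRL3 rose by 1.40 ± 0.15. Of the 16 Pho4 genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, 11 and 1 with the block). Its median was 0.29 (camera adjusted p = 0.00975, adjusted p = 0.193 with an estimated correlation), and VTC1, of polyphosphate synthesis, rose by 1.16 ± 0.15.

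Further lists passed camera in NCB2-FRB cells. Of the 21 cyclin genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone). Its median was 0.49 (camera adjusted p = 2.73e-06, adjusted p = 0.193 with an estimated correlation). The S-phase cyclin gene CLB6 rose by 1.05 ± 0.069 and the G1 cyclin gene CLN2 by 0.88 ± 0.19. Of the 10 histone genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone, 10 and 0 with the block). Its median was 0.42 (camera adjusted p = 0.00196, adjusted p = 0.215 with an estimated correlation), and the linker histone gene HHO1 rose by 0.78 ± 0.085. Of the 24 methionine genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone). Its median was 0.26 (camera adjusted p = 0.00953, adjusted p = 0.246 with an estimated correlation), and MET3 rose by 1.85 ± 0.083. Of the 8 retrograde genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 6 and 1 with the block). Its median was 0.56 (camera adjusted p = 0.00975, adjusted p = 0.265 with an estimated correlation), and the pyruvate carboxylase gene PYC1 rose by 1.05 ± 0.095. Of the 17 glycolysis genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone). Its median was 0.31 (camera adjusted p = 0.00975, adjusted p = 0.268 with an estimated correlation), and print-tip loess gave 0.0729 and the authors' values 0.811. Of the 36 respiratory chain genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone, 17 and 5 with the block). Its median was 0.17 (camera adjusted p = 0.0417, adjusted p = 0.25 with an estimated correlation), and print-tip loess gave 0.0511, external control centring 0.0714 and the authors' values 0.407. QCR8, a complex III subunit gene, rose by 0.87 ± 0.057.

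The lists of ribosomal protein, ribosome biogenesis, MATα-specific, hexose transporter and SAGA subunit genes passed camera downward in NCB2-FRB cells. Of the 126 ribosomal protein genes, 2 rose and 45 fell (2 and 45 adjusted over the list alone, 6 and 72 with the block). Its median was -0.22 (camera adjusted p = 2.05e-07, adjusted p = 0.0399 with an estimated correlation). RPS9A had -0.85 ± 0.11 and RPS16A -0.72 ± 0.099, the latter saturated on 1 untreated array. Of the 49 ribosome biogenesis genes, 3 rose and 26 fell (3 and 29 adjusted over the list alone). Its median was -0.30 (camera adjusted p = 3.7e-06, adjusted p = 0.246 with an estimated correlation), and NOP56 fell (-0.75 ± 0.14). Of the 4 MATα-specific genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone). Its median was -1.01 (camera adjusted p = 0.00689, adjusted p = 0.215 with an estimated correlation). These were MF(ALPHA)2, SAG1 and MF(ALPHA)1. The last was saturated on both untreated and 1 treated NCB2-FRB array, so its change has only a bound and is not given, and it lost its call without untreated culture a (adjusted p = 0.0546). Its value enters the median and the camera test of the list, which were not repeated without it. MF(ALPHA)1 and MF(ALPHA)2 are close in sequence, so their probes may share signal. Of the 16 hexose transporter genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone, 1 and 10 with the block). Its median was -0.19 (camera adjusted p = 0.00975, adjusted p = 0.246 with an estimated correlation), and HXT2 (-0.81 ± 0.16) and HXT1 (-0.71 ± 0.070) fell. Of the 18 SAGA subunit genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, 3 and 9 with the block). Its median was -0.16 (camera adjusted p = 0.0494, adjusted p = 0.246 with an estimated correlation). Without background correction the SAGA camera adjusted p was 0.0537 and with the authors' values 0.114, and print-tip loess, median centring and external control centring also ended the call. GCN5 fell (-0.38 ± 0.083) and SGF11 rose (0.64 ± 0.066).

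The remaining lists did not pass camera in NCB2-FRB cells. Of the 15 phospholipid genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, 7 and 2 with the block) (camera adjusted p = 0.165), and INO1 rose by 1.16 ± 0.23, adjusted p = 0.00314. Of the 37 general initiation genes, 5 rose and 11 fell (5 and 11 adjusted over the list alone, 7 and 18 with the block) (0.0978), and of the 10 galactose genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone) (0.123), with the activator gene GAL4 at -0.58 ± 0.052. Of the 41 Gcn4 genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, 15 and 5 with the block) (0.275, and 0.022 with median centring), and of the 29 glucose-repressed genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone, 10 and 7 with the block) (0.55). Of the 63 meiosis genes, 16 rose and 8 fell (15 and 8 adjusted over the list alone) (0.461), with the sporulation kinase gene SMK1 at 1.08 ± 0.068. Of the 25 pheromone response genes, 4 rose and 4 fell (3 and 4 adjusted over the list alone, 11 and 5 with the block) (0.858), with a median of 0.034 and a mean of -0.017. Of the 7 MATa-specific genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 2 with the block) (0.496), and of the 12 helicase and COS genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 2 and 6 with the block) (0.642). Of the 24 iron regulon genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone, 10 and 4 with the block) (0.496), and the copper chaperone gene ATX1 fell (-0.85 ± 0.080). The medians of the meiosis, glucose-repressed and Gcn4 lists, all within 0.03 of 0, turned negative under print-tip loess or median centring, under median centring, and with the authors' values, in that order.

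**Figure D2:**
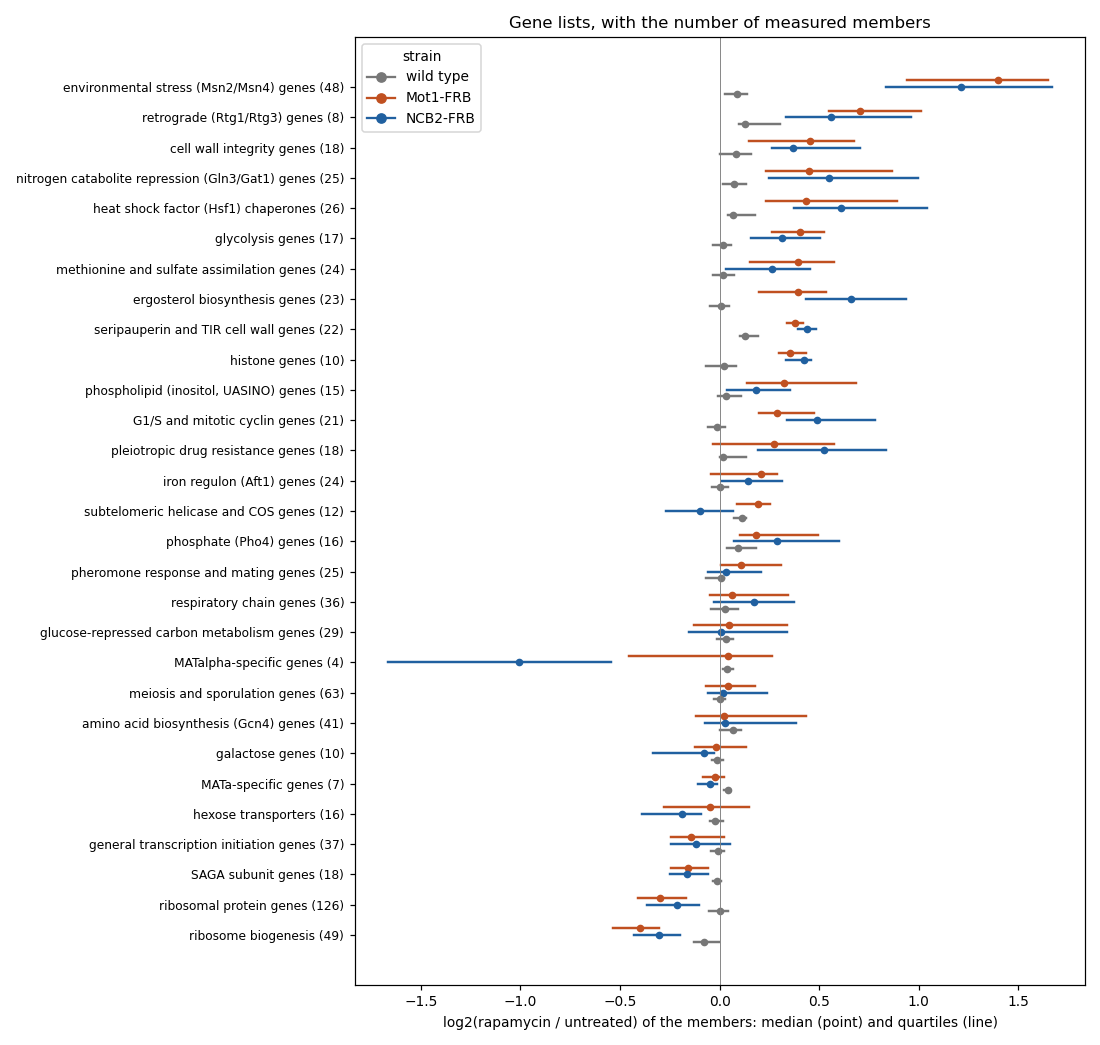
Median log2(rapamycin/untreated) of each of the 29 gene lists on the x axis for Mot1-FRB, NCB2-FRB and wild-type cells, with 1 marker per strain and lines from the lower to the upper quartile of the list's measured members. Environmental stress genes lie at 1.40 in Mot1-FRB, 1.21 in NCB2-FRB and 0.088 in wild-type cells, and lists with medians near 0, such as the Gcn4 list at 0.023 in Mot1-FRB cells, change sign with the scaling (-0.14 with external control centring).

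In wild-type cells, whose factors carry no FRB tag, the same rapamycin treatment gave 0 genes past the threshold in limma, with 118 genes at an unadjusted p under 0.05 against 319.4 expected by chance. The dye difference cancels in this comparison but stays in the SE of the main fit, which makes its p-values conservative. The block, which takes it out, also gave 0, with 555 at an unadjusted p under 0.05. The lack of calls therefore does not show that rapamycin had no effect in wild type. The 5 genes with the smallest p were PYC1 (0.44 ± 0.095), the mitochondrial NADH dehydrogenase gene NDI1 (0.37 ± 0.096), the glutamate dehydrogenase gene GDH3 (0.29 ± 0.076), the RNA polymerase subunit gene RPC19 (-0.29 ± 0.081) and PHM8 (0.28 ± 0.081), with an adjusted p of 1 for each. RPC19 was below the blank spots on all arrays of the Mot1-FRB and NCB2-FRB groups. The SD of log2 changes across genes was 0.0852 in wild type, against 0.404 in Mot1-FRB and 0.429 in NCB2-FRB cells. The array of treated wild-type culture a was dim, with 71.3% of gene probes above the blanks. GAD1, INO1, WSC4, SES1, MTD1, DDR2, HEM13, DAL80, GAL4, TIR3, SMK1, HHO1, SNQ2 and YDL085C-A were below the blanks on it. Leaving out treated culture b gave 1 call, a probe without a gene name (0.79 ± 0.065, adjusted p = 0.0147), and leaving out the dim array with the block gave 1, HSP30, a membrane heat shock gene (0.70 ± 0.060, adjusted p = 0.0178). Both were named after their values were seen.

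List calls in wild type varied by test. No member of the 29 lists passed the limma threshold, and adjusted over the list alone 1 retrograde gene did. Camera called 10 lists: ribosome biogenesis genes had a median of -0.077 (adjusted p = 2.6e-06), seripauperin genes 0.13 (2.66e-05), retrograde genes 0.13 (3.68e-05) and Hsf1 genes 0.066 (0.000129). Nitrogen catabolite repression genes had a median of 0.072 (0.00026), Gcn4 genes 0.065 (0.000757), Pho4 genes 0.093 (0.00138) and environmental stress genes 0.088 (0.00665). Helicase and COS genes had 0.11 (0.00713) and cell wall integrity genes 0.080 (0.0211). All 29 lists had a camera adjusted p of at least 0.261 with an estimated correlation, and fry called 0 of 29. Median centring called 6 lists and turned the Gcn4 median to -0.095 and the cell wall median to -0.095, external control centring added drug resistance genes (0.0335), the authors' values ended the cell wall call (0.115), and 5 lists were called without untreated culture a.

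The rapamycin effects of the tagged strains share no arrays, but the calls share the pooled spread. Across 6388 probes, which are not independent replicates, the effects in Mot1-FRB and NCB2-FRB cells had Pearson r = 0.880 and Spearman rho = 0.834. With the wild-type effect, r was 0.283 for Mot1-FRB and 0.260 for NCB2-FRB cells. Between letters a and b the wild-type effect itself had r = 0.216, against 0.967 in Mot1-FRB and 0.917 in NCB2-FRB cells. This low agreement limits any correlation with the wild-type effect. Of the genes called, 1085 rose in both strains, 77.3% of the Mot1-FRB and 74.6% of the NCB2-FRB rises. Independent lists, which these are not, would share 319.3. Another 682 fell in both, against 178.1, and 10 were called in opposite directions, against 478.0. RTC3, HSP26, CAR2, MSC1, WSC4 and BDH2 were among the shared rises, and MF(ALPHA)2, SES1 and YMR321C among the shared falls.

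**Figure D3:**
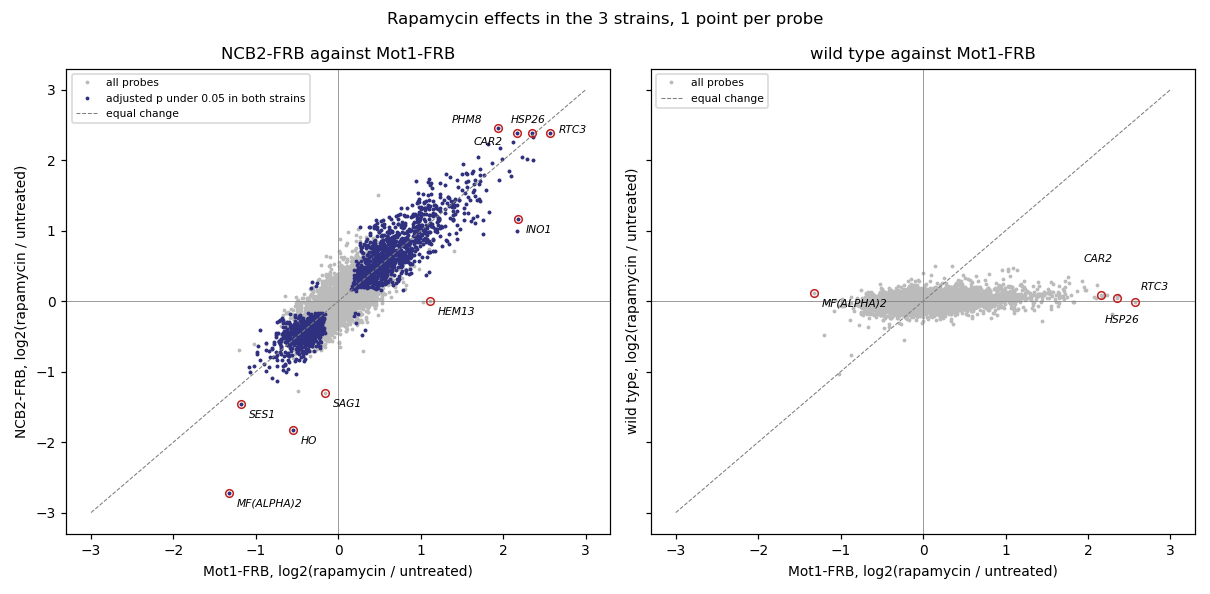
Log2(rapamycin/untreated) in NCB2-FRB cells (left, y axis) and in wild-type cells (right, y axis) against Mot1-FRB cells (x axes), with 1 point per probe (6388) and genes called in both tagged strains in blue. Points follow the line of equal change on the left (r = 0.880) and lie along the x axis on the right (r = 0.283), and MF(ALPHA)2, HO, SAG1 and HEM13 lie off the line.

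Effects beyond those of rapamycin alone were tested as differences from wild type. In Mot1-FRB cells 811 genes had a higher and 428 a lower response than wild type. RTC3 exceeded wild type by 2.58 ± 0.32, adjusted p = 0.00121, HSP12 by 2.47 ± 0.42, HSP26 by 2.31 ± 0.38, GAD1 by 2.29 ± 0.19 and MSC1 by 2.27 ± 0.28. Responses lower than in wild type included MF(ALPHA)2 (-1.44 ± 0.20, adjusted p = 0.00193), YMR321C (-1.08 ± 0.11), NOP56 (-1.02 ± 0.20), TRM112 (-0.95 ± 0.12) and UTP14 (-0.93 ± 0.13). Of the 2381 genes called in Mot1-FRB, 1235 (51.9%) also differed from wild type in the same direction, and 613 of the 734 changed at least 1.5-fold did. The block gave 1624 higher and 1231 lower, median centring 11 and 0, and centring on external controls 369 and 689, with a shift of the median of all genes of -0.18. Without untreated wild-type culture a the count was 825, without untreated Mot1-FRB culture a 824, and without culture b 818.

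In NCB2-FRB cells 927 genes had a higher and 572 a lower response than wild type. RTC3 exceeded wild type by 2.39 ± 0.32, adjusted p = 0.00116, HSP26 by 2.34 ± 0.38, CAR2 by 2.31 ± 0.20, MTD1 by 2.23 ± 0.19 and MSC1 by 2.23 ± 0.28. MF(ALPHA)2 (-2.84 ± 0.20, adjusted p = 0.000142), HO (-1.90 ± 0.15), SAG1 (-1.36 ± 0.19), AAP1 (-1.18 ± 0.16) and SES1 (-1.44 ± 0.39, adjusted p = 0.026) had lower responses. SPT15 exceeded wild type by 0.38 ± 0.10, adjusted p = 0.0244. Of the 2617 genes called in NCB2-FRB, 1495 (57.1%) also differed from wild type in the same direction. The block gave 1631 higher and 1459 lower, median centring gave 24 and 3, and external control centring called 979 in all. SES1 lost its call without untreated wild-type culture b, treated wild-type culture a, untreated NCB2-FRB culture a or treated NCB2-FRB culture b (adjusted p up to 0.0908). SPT15 lost it without either untreated wild-type culture, treated wild-type culture a, either untreated NCB2-FRB culture or treated NCB2-FRB culture b (up to 0.0872).

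All 29 lists were also tested for a difference from wild type, and 4 that passed in both strains are given here, with the values of Mot1-FRB first. Both tests use the same wild-type arrays and are not independent of each other. Of 48 environmental stress genes, 35 had a higher response in Mot1-FRB and 35 in NCB2-FRB cells (42 and 38 adjusted over the list alone), with medians of 1.34 and 1.11 (camera adjusted p = 5.14e-18 and 1.07e-14, and adjusted p = 0.264 and 0.32 with an estimated correlation). Of 126 ribosomal protein genes, 31 and 32 had a lower response (37 and 32 adjusted over the list alone, 64 and 57 with the block, camera adjusted p = 1.39e-12 and 6.6e-07), and this list held with an estimated correlation, with adjusted p = 0.0087 and 0.0484. Of 23 ergosterol genes, 8 and 18 had a higher response (12 and 20 adjusted over the list alone, 15 and 22 with the block, camera adjusted p = 0.000315 and 3.52e-09, and adjusted p = 0.264 and 0.129 with an estimated correlation). Of 21 cyclin genes, 6 and 11 had a higher response (6 and 14 adjusted over the list alone, 13 and 18 with the block, camera adjusted p = 0.0014 and 3.02e-06, and adjusted p = 0.264 and 0.235 with an estimated correlation). Some lists called within a strain did not pass against wild type. In Mot1-FRB cells these were the seripauperin and TIR (camera adjusted p = 0.0929) and Pho4 lists (0.196). In NCB2-FRB cells they were the SAGA (camera adjusted p = 0.086), retrograde (0.086), Pho4 (0.064) and respiratory chain lists (0.136).

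The responses of the tagged strains differed from each other for 32 genes, 14 with a higher value in Mot1-FRB and 18 in NCB2-FRB cells. HEM13, a heme biosynthesis gene, rose in Mot1-FRB (1.11 ± 0.063) with a value of 0.0044 ± 0.063 in NCB2-FRB cells, a difference of 1.10 ± 0.089, adjusted p = 0.00368. MF(ALPHA)2 (1.40 ± 0.20, adjusted p = 0.0463), HO (1.28 ± 0.15, adjusted p = 0.0159) and SAG1 (1.15 ± 0.19, adjusted p = 0.0463) had lower responses in NCB2-FRB cells, and HO also fell in Mot1-FRB cells (-0.55 ± 0.10, adjusted p = 0.00335). AUS1, a sterol importer gene, differed by 0.76 ± 0.13. The mitotic cyclin gene CLB2 (-0.71 ± 0.075, adjusted p = 0.0159), the bud site gene BUD9 (-0.86 ± 0.15), the daughter-specific gene DSE3 (-0.86 ± 0.14), OLA1 (-0.80 ± 0.13) and the homoserine dehydrogenase gene HOM6 (-0.73 ± 0.11) had lower values in Mot1-FRB cells. INO1 (1.02 ± 0.32, adjusted p = 0.186) and SPT15 (-0.28 ± 0.10, adjusted p = 0.243) had an adjusted p of 0.0237 and 0.0396 with the block.

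The number of such genes depended on the fit and on the arrays that entered it. Wild-type arrays do not enter this difference, and without untreated culture a HEM13 (1.10) and HO (1.28) kept their values. Leaving out a wild-type array thus moved the count through the shared spread and the degrees of freedom only. With the block, no array but the dim wild-type one was left out. The block called 1048 (549 higher and 499 lower in Mot1-FRB), no background correction 7 and 1, external control centring 2 and 12, and median centring 0. Without untreated wild-type culture a or b the count was 4, without treated wild-type culture a or b 1, without untreated Mot1-FRB culture a or b 1, without treated Mot1-FRB culture a 3 and b 2, without untreated NCB2-FRB culture a or b 1, and without treated NCB2-FRB culture a 10 and b 2. HEM13 kept its call without each of the 12 arrays in turn (adjusted p up to 0.0448), and of the 13 named genes it was the only 1 to do so. HO lost it without 7 of the 12 (up to 0.12), and MF(ALPHA)2 and SAG1 whichever array was left out (up to 0.172 and 0.191). The remaining named calls, those of ARG4, GAS2 and CLB6 included, ended without at least 9 of the 12 (up to 0.192).

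Between the tagged strains these lists passed camera, none with an estimated correlation. Of 4 MATα-specific genes, 2 were higher in Mot1-FRB cells (4 adjusted over the list alone and 4 with the block), with median 1.08, camera adjusted p = 5.37e-06, adjusted p = 0.134 with an estimated correlation. The saturated MF(ALPHA)1 is among the 4, and its value enters this median and test, which were not repeated without it. Of 23 ergosterol genes, 0 passed over all genes and 6 were lower in Mot1-FRB adjusted over the list alone (11 with the block), with median -0.33, camera adjusted p = 9.16e-09, adjusted p = 0.134 with an estimated correlation. Of 21 cyclin genes, 2 were lower, CLB2 and CLB6 (-0.58 ± 0.097, adjusted p = 0.0463), and 2 adjusted over the list alone (9 with the block), with median -0.20, camera adjusted p = 0.000735, adjusted p = 0.281 with an estimated correlation. Camera also called ribosome biogenesis (median -0.14, camera adjusted p = 6.61e-05, adjusted p = 0.33 with an estimated correlation), drug resistance (median -0.16, camera adjusted p = 0.00112, adjusted p = 0.44 with an estimated correlation), phospholipid (median 0.20, camera adjusted p = 0.0043, adjusted p = 0.281 with an estimated correlation) and hexose transporter genes (median 0.22, camera adjusted p = 0.00572, adjusted p = 0.281 with an estimated correlation). It called nitrogen catabolite repression (median -0.13, camera adjusted p = 0.0147, adjusted p = 0.284 with an estimated correlation), galactose (median 0.15, camera adjusted p = 0.0394, adjusted p = 0.281 with an estimated correlation), ribosomal protein (median -0.048, camera adjusted p = 0.04, adjusted p = 0.281 with an estimated correlation), helicase and COS (median 0.23, camera adjusted p = 0.04, adjusted p = 0.281 with an estimated correlation) and methionine genes (median 0.11, camera adjusted p = 0.0396, adjusted p = 0.371 with an estimated correlation, camera adjusted p = 0.0668 with the block). Single members of other lists passed: the arginine gene ARG4 (0.67 ± 0.077, adjusted p = 0.0159) and the spore wall gene GAS2 (-0.47 ± 0.078, adjusted p = 0.0463).

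Without rapamycin, Mot1-FRB cells differed from wild type in 62 genes, 55 higher and 7 lower. MED6, a Mediator subunit gene, was higher by 1.27 ± 0.076, adjusted p = 0.000272, HSP26 by 1.84 ± 0.27, adjusted p = 0.0212, the sterol-binding protein gene PRY1 by 1.33 ± 0.25, adjusted p = 0.0458, YIR042C by 1.42 ± 0.16 and YLL053C by 1.10 ± 0.12. MOT1 was higher by 0.67 ± 0.095, adjusted p = 0.0209, PHM8 by 0.71 ± 0.081, PUT1 by 0.86 ± 0.15 and the amino acid permease gene GAP1 by 0.68 ± 0.11. HO (-0.64 ± 0.11, adjusted p = 0.0325), GDS1 (-0.56 ± 0.096), the tRNA splicing gene SEN54, a neighbour of MOT1 (-0.52 ± 0.072), CLD1 (-0.43 ± 0.072) and the phospholipid activator gene INO2 (-0.42 ± 0.073) were lower. NCB2 had 0.44 ± 0.18, adjusted p = 0.461 and SPT15 0.24 ± 0.071, adjusted p = 0.231, and with the block their adjusted p were 0.00096 and 0.0309. In NCB2-FRB cells without rapamycin, 1 gene passed, MED6 (1.27 ± 0.076, adjusted p = 0.000274), with 127 genes at an unadjusted p under 0.05. Both tag comparisons use the same untreated wild-type arrays, so MED6 was not called independently in them. NCB2 had -0.65 ± 0.18, adjusted p = 1, and it was the second gene called with the block (adjusted p = 0.000273, 1 higher and 1 lower), print-tip loess (0.0385) and the authors' values (0.000294).

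The untreated Mot1-FRB count depended on the fit and on the arrays that entered it. Leaving out a treated wild-type or an NCB2-FRB array changes no value in this comparison, only the shared spread and the degrees of freedom. The block called 320 higher and 127 lower, external control centring 146 and 0 with a shift of the median of all genes of 0.16, the authors' values 203 and 66, and median centring 2 and 0, MED6 and the kynurenine monooxygenase gene BNA4 (1.04 ± 0.098). The count was 2 without untreated wild-type culture a, 12 without b, 37 without treated wild-type culture a or b, 2 without untreated Mot1-FRB culture a, 10 without b, and 31 without untreated NCB2-FRB culture a or b. MED6 kept its call without each of the 12 arrays in both comparisons (adjusted p up to 0.00777 and 0.00784), and the MOT1 and HSP26 calls ended without each of the 4 untreated wild-type and Mot1-FRB arrays (up to 0.165 and 0.215). The other calls named in this comparison ended without between 2 and 10 of the 12 arrays (up to 0.342).

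In untreated Mot1-FRB no list passed with an estimated correlation. Of 25 nitrogen catabolite repression genes, 4 were higher (9 adjusted over the list alone, 9 with the block), with median 0.22, camera adjusted p = 2.26e-10, adjusted p = 0.0825 with an estimated correlation. Of 48 environmental stress genes, 1 was higher (4 adjusted over the list alone, 8 with the block), with median 0.31, camera adjusted p = 1.88e-09, adjusted p = 0.496 with an estimated correlation. Of 23 ergosterol genes, 1 was higher, ERG3 (0.45 ± 0.078), and 4 adjusted over the list alone (7 with the block), with median 0.20, camera adjusted p = 3.4e-06, adjusted p = 0.217 with an estimated correlation. Of 24 methionine genes, 2 were higher (2 adjusted over the list alone, 5 with the block), MET14 (0.56 ± 0.090) and MET3 (0.52 ± 0.083), with median 0.12, camera adjusted p = 6.77e-05, adjusted p = 0.225 with an estimated correlation. Camera also called histone (median 0.19, camera adjusted p = 6.77e-05, adjusted p = 0.217 with an estimated correlation), iron regulon (median 0.15, camera adjusted p = 0.000307, adjusted p = 0.496 with an estimated correlation), retrograde (median 0.19, camera adjusted p = 0.00754, adjusted p = 0.452 with an estimated correlation) and ribosome biogenesis genes (median -0.083, camera adjusted p = 0.00627, adjusted p = 0.542 with an estimated correlation). It called glycolysis (median 0.12, camera adjusted p = 0.0129, adjusted p = 0.485 with an estimated correlation), respiratory chain (median 0.051, camera adjusted p = 0.0129, adjusted p = 0.386 with an estimated correlation), drug resistance (median 0.095, camera adjusted p = 0.0145, adjusted p = 0.578 with an estimated correlation), cell wall integrity (median 0.13, camera adjusted p = 0.0258, adjusted p = 0.557 with an estimated correlation) and MATα genes (median 0.17, camera adjusted p = 0.0472, adjusted p = 0.452 with an estimated correlation, camera adjusted p = 0.0859 with the block). With the block, seripauperin (camera adjusted p = 0.0228) and cyclin genes (0.0143) passed too. In untreated NCB2-FRB cells 0 list members passed in limma over all genes and 2 iron regulon genes did adjusted over the list alone, with median 0.15, camera adjusted p = 2.56e-09, adjusted p = 0.322 with an estimated correlation for that list. Camera called 11 other lists there, all with medians within 0.11 of 0 and adjusted p of at least 0.306 with an estimated correlation, and the block ended the calls of glycolysis (0.0686) and pheromone response genes (0.0638).

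**Figure D4:**
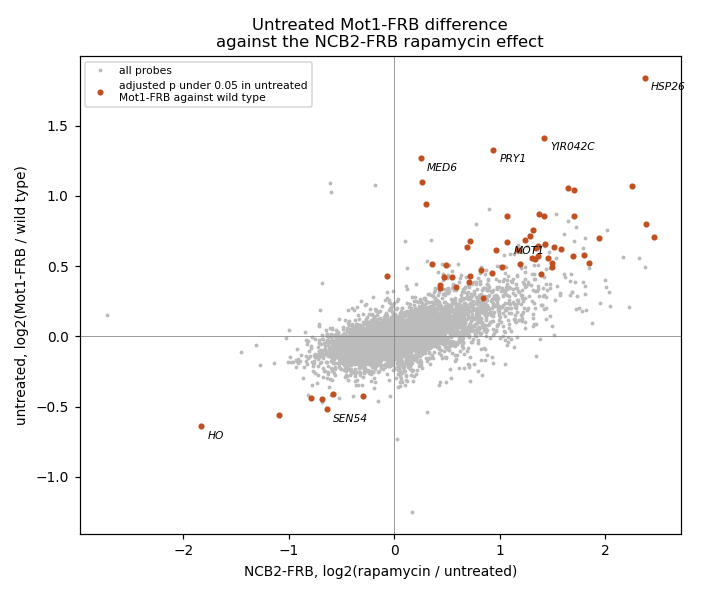
Difference between untreated Mot1-FRB and wild-type cells (y axis, log2) against the rapamycin effect in NCB2-FRB cells (x axis, log2), 1 point per probe (6388). The effects share no arrays, and the 62 genes called in untreated Mot1-FRB cells are orange. Of these, 52 of the 55 higher genes also rose and 7 of the 7 lower genes also fell in NCB2-FRB cells with rapamycin (r = 0.652 over all probes), and HSP26 lies at the upper right.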

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

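In this part the tests of explanations were all chosen after the values were seen, while the comparisons between strains were fixed before the data were examined. The rapamycin effect differed between Mot1-FRB and wild type in 1239 genes, between NCB2-FRB and wild type in 1499, and between the tagged strains in 32, each by limma on the difference of effects. These differences between strains are what singles the results out.

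Against wild type, the response of Mot1-FRB cells was higher for RTC3 (2.58 ± 0.32), HSP12 (2.47 ± 0.42), HSP26 (2.31 ± 0.38), GAD1 (2.29 ± 0.19), MSC1 (2.27 ± 0.28) and MOT1 (1.09 ± 0.13). It was lower for MF(ALPHA)2 (-1.44 ± 0.20), YMR321C (-1.08 ± 0.11), NOP56 (-1.02 ± 0.20), TRM112 (-0.95 ± 0.12) and UTP14 (-0.93 ± 0.13). The response of NCB2-FRB cells was higher for RTC3 (2.39 ± 0.32), HSP26 (2.34 ± 0.38), CAR2 (2.31 ± 0.20), MTD1 (2.23 ± 0.19), MSC1 (2.23 ± 0.28), MOT1 (1.07 ± 0.13) and SPT15 (0.38 ± 0.10). It was lower for MF(ALPHA)2 (-2.84 ± 0.20), HO (-1.90 ± 0.15), SES1 (-1.44 ± 0.39), SAG1 (-1.36 ± 0.19) and AAP1 (-1.18 ± 0.16). Mot1-FRB minus NCB2-FRB was above 0 for MF(ALPHA)2 (1.40 ± 0.20), HO (1.28 ± 0.15), SAG1 (1.15 ± 0.19), HEM13 (1.10 ± 0.089) and AUS1 (0.76 ± 0.13). It was below 0 for BUD9 (-0.86 ± 0.15), DSE3 (-0.86 ± 0.14), OLA1 (-0.80 ± 0.13), HOM6 (-0.73 ± 0.11) and CLB2 (-0.71 ± 0.075).

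MOT1 and NCB2 transcripts rose with rapamycin in both tagged strains. An effect of the tag at the gene's own locus would leave the untagged gene unchanged, but the smaller change of an untagged gene was 0.778 ± 0.177, that of NCB2 in Mot1-FRB cells. Rapamycin without depletion would raise them in wild type, where the larger change was 0.000755 ± 0.0946, and a shift of the array scale would remove the rise under external control centring, where the smallest of the 4 changes was 0.617 ± 0.162. A shared rise of initiation genes would give that list a median above 0, and the larger of its medians was -0.116. The cause of the rise was left open by these tests, and for NCB2 the excess over wild type had limma adjusted p = 0.0558 in Mot1-FRB and 0.0945 in NCB2-FRB, and passed in both with the letter as a block (2.49e-05 and 4.28e-05), with print-tip loess and with the authors' values.

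The rapamycin responses of MF(ALPHA)2, SAG1 and HO were lower in NCB2-FRB than in Mot1-FRB cells. Cross-hybridisation between the α-factor genes would not reach SAG1 and HO, whose smaller difference was 1.15 ± 0.186, and this does not apply to MF(ALPHA)2 itself. A share of MATa cells in the treated NCB2-FRB cultures would raise MATa-specific genes, whose median was -0.0473. SAG1 and HO differed by at least 0.989 ± 0.201 in 5 scalings (SAG1, external controls, adjusted p = 0.0567). Median centring gave 1.12 and 1.29 (adjusted p = 1), and HO passed in the rest. The cause was left open. SAG1 lost its call whichever array was left out, while its difference stayed between 0.995 and 1.30 in these runs.

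Untreated Mot1-FRB cells differed from wild type in 62 genes, and 52 of the 55 higher and 7 of the 7 lower were called the same way in NCB2-FRB cells with rapamycin, on other arrays. An intensity trend would give no relation among genes of like brightness, and the lowest r over 4 equal intensity parts was 0.634. A chance state of 1 culture would show in 1 letter only, and the lower r of a culture with the other letter's effect was 0.546. Partial loss of Mot1 function by the tag would make the difference resemble a depletion, and r over all genes was 0.652. Another growth state would lower r without the 274 growth and stress genes of the lists, and r was 0.640. Many other genes may move too, so this does not exclude it.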

How the results depend on the processing

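Alternatives were fixed beforehand, except the combinations with the block and the choice of bright external control probes, chosen after seeing the results. Dim signal on 1 array limits the wild-type comparison, and 2 arrays per group limit all of them. The correlation of the rapamycin effects (0.880) stayed between 0.838 and 0.886 under the alternatives for which it was computed, which leave out the fit of only the groups compared and the 1.5-fold limit. Counts in this part are given in the order Mot1-FRB, NCB2-FRB, Mot1-FRB against wild type, NCB2-FRB against wild type, Mot1-FRB against NCB2-FRB, untreated Mot1-FRB, untreated NCB2-FRB, and called in both tagged strains, and the main counts are 2381, 2617, 1239, 1499, 32, 62, 1 and 1767. Wild type had 0 genes except where given.

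With the letter as a block, the counts were 3982, 4001, 2855, 3090, 1048, 447, 2 and 3025. With the block and the dim wild-type array left out they were 4010, 4011, 2555, 2777, 1017, 461, 2 and 3025, with 1 in wild type, and with the block and the authors' values 3869, 3999, 2855, 3020, 826, 378, 2 and 2986. Where its value is not printed, the block changed some list counts but no other call in the text. Median centring gave 507, 696, 11, 27, 0, 2, 1 and 382, with a correlation of 0.853. The authors' values gave 3621, 3693, 2487, 2700, 542, 269, 2 and 2746. A change of at least 1.5-fold left 734, 848, 590, 742, 20, 30, 1 and 539. External control centring gave 979 for NCB2-FRB against wild type, 14 for the tagged strains against each other and 146 for untreated Mot1-FRB, and shifted the median of all genes by -0.16 in Mot1-FRB and by 0.16 and 0.10 in untreated Mot1-FRB and NCB2-FRB, and by -0.18 and -0.16 in Mot1-FRB against wild type and NCB2-FRB. The tagged strains differed in 8 genes without background correction, 101 with print-tip loess (which gave 2 in untreated NCB2-FRB), 6 without the 25% dimmest probes and 1 with only the groups compared, which gave 28 in untreated Mot1-FRB. The value of BUR6 in Mot1-FRB reversed with external control centring (-0.0096, adjusted p = 0.941). Fewer probes or arrays enter some of these fits by construction, the block takes the dye difference out of the spread, and otherwise the cause was not tested.

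With each array left out in turn, the counts ranged over 1656 to 2528, 1870 to 2590, 818 to 1357, 1030 to 1534, 1 to 10, 2 to 81, 1 to 1 and 1353 to 1715, with 0 to 1 in wild type and a correlation of 0.838 to 0.880. A lone culture is then assumed to vary like the other groups. Its group also holds 1 dye orientation only, and these runs had no dye term. Calls and counts that move may therefore reflect the dye as well as the culture left out. Of the named calls, 83 of 107 in Mot1-FRB, 96 of 116 in NCB2-FRB, 54 of 76 and 67 of 91 against wild type, 1 of 13 between the tagged strains and 1 of 21 in untreated Mot1-FRB held without each array.

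Camera called 16 lists in Mot1-FRB, 19 in NCB2-FRB and 10 in wild type. With an estimated correlation it called 1, 1 and 0, fry called 0 in wild type (23 and 24 in the tagged strains), and median centring left 6 in wild type. With each array left out, 15 to 17, 17 to 19 and 5 to 11 lists were called. Of the named-gene values, which include some without a call in the main analysis, 292 kept their direction but lost their call and 155 stayed on the same side of the threshold in the same direction with median centring, 51 and 394 with external control centring, 12 and 429 with the authors' values, 19 and 428 with print-tip loess, 12 and 437 without background correction, 41 and 410 with only the groups compared, and 0 and 442 with the block, where 9 gained a call. Tests of TATA elements and chromosome ends and a slide or scan block were planned and not run.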

Other observations

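The gene groups in this part, and all the genes named for them, were chosen after the values were seen and were not tested as groups. Over all 6388 genes, 978 fell in Mot1-FRB and 1163 in NCB2-FRB cells with rapamycin. Of 18 cytosolic aminoacyl-tRNA synthetase genes, 0 rose and 9 fell in Mot1-FRB cells (median -0.31) and 1 rose and 6 fell in NCB2-FRB cells (median -0.21), with a median of 0.045 in wild type. The methionyl-tRNA synthetase gene MES1 fell in both (-0.65 ± 0.091 and -0.72 ± 0.091). The valyl gene VAS1 had -0.67 ± 0.089 and -0.37 ± 0.089, and the lysyl gene KRS1 rose in NCB2-FRB cells (0.45 ± 0.072). Of 31 tRNA modification genes, 1 rose and 19 fell in Mot1-FRB (median -0.35) and 3 rose and 22 fell in NCB2-FRB cells (median -0.33). The dihydrouridine synthase gene SMM1 had -0.85 ± 0.082 and -0.93 ± 0.082, the tRNA 2'-phosphotransferase gene TPT1 -0.80 ± 0.12 and -0.79 ± 0.12, and the deaminase gene TAD2 rose (0.47 ± 0.12 and 0.59 ± 0.12).

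Of 9 methionine salvage genes, 1 rose and 6 fell in Mot1-FRB (median -0.57) and 1 rose and 7 fell in NCB2-FRB cells (median -0.44). The isomerase gene MRI1 fell (-0.64 ± 0.099 and -0.89 ± 0.099) and the dioxygenase gene ADI1 rose (0.62 ± 0.14 and 0.59 ± 0.14). Of 10 glycine cleavage and folate genes, 5 rose and 2 fell in Mot1-FRB (median 0.44) and 6 rose and 2 fell in NCB2-FRB cells (median 0.63). The glycine decarboxylase subunit gene GCV1 rose (1.52 ± 0.086 and 1.94 ± 0.086), and the dihydrofolate reductase gene DFR1 (-0.90 ± 0.12 and -0.90 ± 0.12) and the folate synthase gene MIS1 (-0.61 ± 0.17 and -0.96 ± 0.17) fell. Of 4 arginine and proline degradation genes, 4 rose in Mot1-FRB (median 1.06) and 3 in NCB2-FRB cells (median 1.51), among them the arginase gene CAR1 (1.19 ± 0.093 and 1.32 ± 0.093). These groups were picked from 10 name patterns looked at after the largest changes were known.

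MED6, higher in both untreated tagged strains than in wild type, also rose with rapamycin in Mot1-FRB (0.31 ± 0.076, adjusted p = 0.0111) and NCB2-FRB cells (0.25 ± 0.076, adjusted p = 0.0247), and had 0.0014 ± 0.076 in wild type. Whether its locus is altered in the parent of the tagged strains was not tested, so its difference without rapamycin is not assigned to the tags. The untreated NCB2-FRB difference had r = 0.25 with the rapamycin effect of Mot1-FRB cells. The 4 bright external control probes had a median log2 change of 0.187 in Mot1-FRB, -0.0126 in NCB2-FRB and -0.0225 in wild-type cells with rapamycin. Their ranges were 0.0451 to 0.246, -0.225 to 0.247 and -0.0579 to 0.0538. In NCB2-FRB cells the values rose as intensity fell, so the median hides opposite changes.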
